A study of Nothobranchius furzeri with 16 samples.

How the data were processed

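The study measured the transcriptome of 16 individual killifish brains, 8 from fish injected with bortezomib and 8 from fish injected with vehicle. Per the labels' protocols, fish of one hatch were allocated at random, both sexes were in each group, brains were sonicated and spun, and RNA was taken from the aqueous phase of 150 µl of the homogenate. The sex of each fish and any library batch are not given in the sources used here. The submitters' processing notes name bcl2fastq 2.20.0.422 and STAR. The read counter, the genome build and the annotation are not given in the sources used here.

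The authors deposited 1 table with TPM values, per the values themselves: each column summed to 1000000, and low values of a gene were whole multiples of a step that differed between genes, so that gene length had been divided out. In a check of 2818 low values, 94.3% were whole multiples within 0.05 reads of a whole number, where chance gives 10%. TPM keeps no absolute depth, so no counting intervals are given. The relative depth of each fish was recovered from the ratio of these steps between fish. The table held 26739 rows. For 5137 of them the symbol was the row's own identifier, and 5987 rows shared a symbol with another row. Gene symbols come from the file. None of its identifiers was found in the RefSeq gene table of the species (0 matches), so no coordinates are given. Rows that share a symbol can be duplicates or parts of 1 gene whose reads were split, and their values are uncertain. No pair of columns was identical, and the correlation between fish over all tested genes was 0.928 to 0.981.

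The design fixed before the data were examined assumed gene counts and a count-based test. The values are TPM, so the test named there for normalized values was used: limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(TPM + 1). A fold change is thus on the log2(TPM + 1) scale and understates the change of low genes. Genes with at least 1 TPM in at least 8 fish were tested (18529; 8210 rows were left out), with no rescaling between fish and no covariate. P-values were two-sided and adjusted by Benjamini-Hochberg with a threshold of 0.05. Values in the text are means ± SD over 8 fish, and errors of log2 fold changes are standard errors. On simulated data for this comparison, with 18529 genes of which 200 were changed, 48% of the genes changed by 0.5 (log2) and 82% of those changed by 1 were called, with 8 false calls. The simulation drew each gene independently of the others and held no component shared between genes. These rates may thus not hold for the real values.

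Before the data were examined, 35 gene lists were fixed, of pathways and of markers of brain cell types and neighbouring tissues, each with at least 5 tested genes. Symbols were matched in lower case, with fish duplicate suffixes allowed; a few matches are wrong, such as the GTPases RHOA and RHOB in the retina list. Lists were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the 35 lists. Of 20 lists called, 8 higher and 12 lower, 3 held with an estimated correlation: proteasome subunits, proteasome assembly and stress factors, and immediate early genes. A list score per fish is the mean over its genes of log2(TPM + 1) centred on all fish. Single values were compared by two-sided exact permutation tests over 12870 splits. Lists that overlap share genes, so their tests are not independent.

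The genes named were chosen by a rule fixed beforehand: the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 TPM and a gene symbol, the 3 members with the smallest p in each called list, and a set fixed in advance. Of that set, NFE2L1A and 1 of the HMOX1 models fell under the TPM minimum and were not tested. Alternatives were another scaling of the values, other filters and pseudocounts, covariates for depth and for hidden components, sample weights, a robust variance estimate, a replicate block, other set tests, and leaving out each fish. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.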

Results

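RNA was sequenced from individual brains of adult turquoise killifish (Nothobranchius furzeri), a short-lived annual fish used to study ageing. Fish of 12 to 14 weeks post hatch received 5 intraperitoneal injections over 4 weeks, on days 0, 6, 12, 18 and 24. The 8 fish of the treated group received bortezomib at 500 µM, a peptide boronate that binds the beta 5 subunit of the proteasome and blocks its main proteolytic site. The 8 fish of the control group received the vehicle, 1% DMSO in salt solution, at the same volume of 10 µl per g of body weight. The design has 1 contrast, and it asks how the brain transcriptome differs after a proteasome inhibitor has been given to the living animal. Proteasome activity is not among the values used here. The values are TPM, transcript abundances scaled to the same total of 1000000 in each fish, for 26739 gene models. The total read count per fish is unknown. The relative depth recovered from low values ran from 0.863 to 1.39 between fish, with 0.991 ± 0.0778 in bortezomib fish and 1.02 ± 0.163 in vehicle fish (SD, n = 8 each; two-sided exact permutation p = 0.712).

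Transcripts of the proteasome and of the factors that assemble it rose in the brains of bortezomib fish, and immediate early genes fell. PSMA4, a subunit of the 20S core, stood at 209 ± 14.3 TPM in bortezomib fish and 110 ± 2.45 TPM in vehicle fish (SD, n = 8 each). FOS, an activity-induced transcription factor, stood at 13.9 ± 2.73 TPM against 45.4 ± 13.8 TPM. Of 18529 genes tested, 669 were higher and 232 lower in bortezomib fish (limma on log2(TPM + 1), Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were 2635 higher and 1285 lower. Most changes were small: the median size of the called changes was 0.45 on the log2 scale, and 21 calls in each direction reached 2-fold. In 200 genes every bortezomib fish lay above every vehicle fish and in 41 every bortezomib fish lay below, where chance would give 1.44 genes, or 0.00777%, in each direction. The excess of rises depended on the scale of the values, with 535 higher and 386 lower after median-of-ratios scaling, 500 and 397 after upper-quartile scaling, and 549 and 563 after quantile normalization. The number of calls fell from 901 to 487 without bortezomib replicate 6 and to 534 without bortezomib replicate 4. It fell to 579 without vehicle replicate 7, and to 327 without the 4 fish whose brains carried pituitary hormone transcripts. In that last fit 28 of the 67 calls of named genes ended, 17 with a smaller and 11 with a larger change. No other set of 4 fish was left out for comparison, so the part that fewer fish play is unknown.

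Proteasome subunits rose almost without exception. Of 38 gene models for subunits of the 20S core and the 19S regulatory particle, 37 were higher, 0 were lower and 1 did not pass the test; adjusted over the list alone the count was also 37. The median rise was 1.64-fold. PSMA4 rose by 0.91 ± 0.05 (log2 fold change ± SE, adjusted p = 1.05e-08), and PSMD7 and PSMA3 by 0.95 ± 0.06 and 0.89 ± 0.06. PSMB5, the subunit that bortezomib binds, rose from 192 ± 16.5 to 272 ± 37.5 TPM (log2 fold change 0.50 ± 0.08, adjusted p = 0.00198). The largest rises were those of PSMD8 (1.05 ± 0.16) and PSMA6A (1.03 ± 0.09). The duplicates of a lid subunit differed: PSMD11B rose by 0.71 ± 0.06, while PSMD11A had a log2 fold change of 0.15 ± 0.13 (adjusted p = 0.528). It was 0.076 without vehicle replicate 6 and 0.24 without bortezomib replicate 8, and the difference between the 2 copies was not tested. In 32 of the 38 models every bortezomib fish lay above every vehicle fish. The competitive set test camera called the list (adjusted p = 2.15e-66), also with an estimated correlation between genes (adjusted p = 0.00768). The list score per fish, the mean centred log2 value of its genes, was 0.16 to 0.49 in bortezomib fish and -0.46 to -0.28 in vehicle fish (two-sided exact permutation p = 0.0001554, the smallest that 12870 splits allow).

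**Figure D1:**
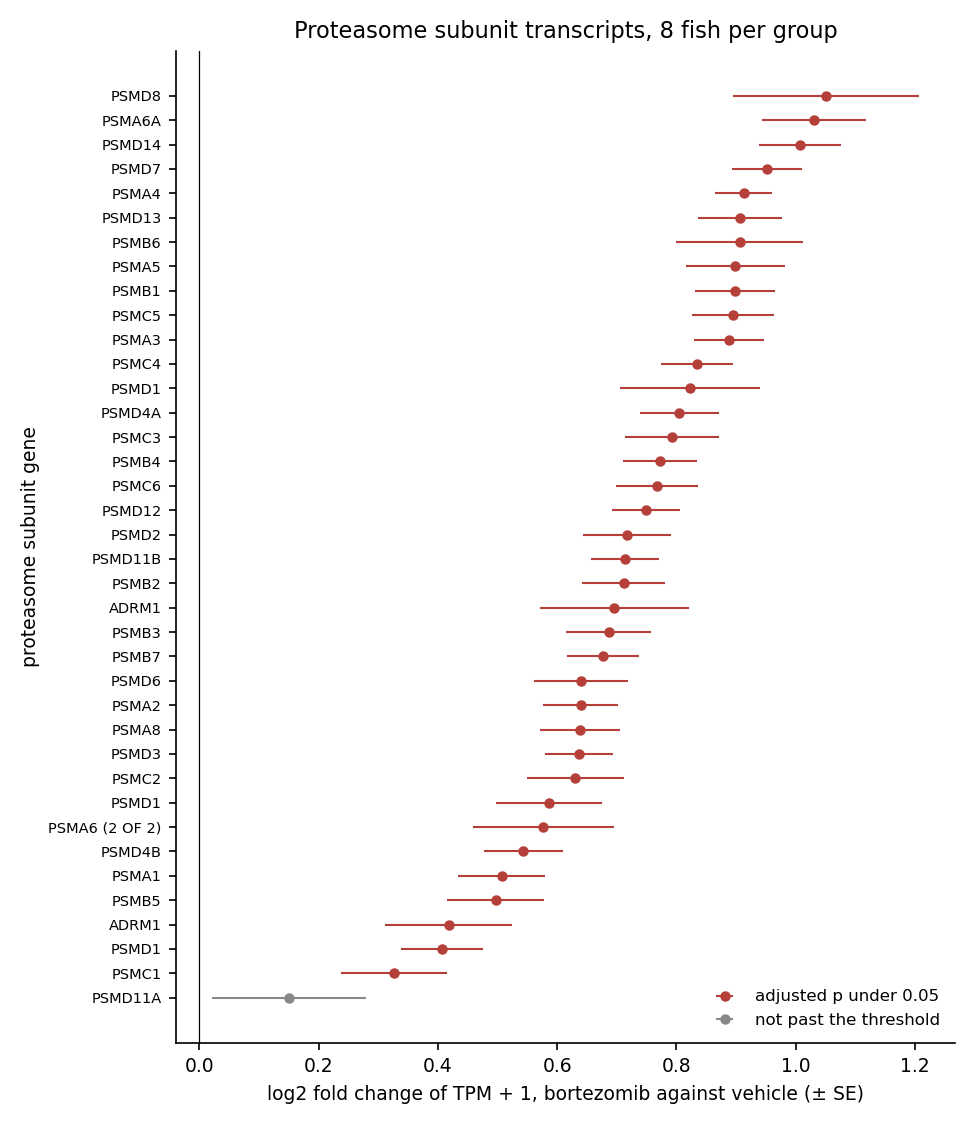
Log2 fold change (x axis, of TPM + 1, bortezomib against vehicle, 8 fish per group) of each of the 38 proteasome subunit gene models (y axis), with bars of 1 standard error. The 37 red points passed the adjusted threshold and the grey point, PSMD11A, did not.

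Most listed factors that assemble the proteasome or work beside it rose too. Of 20 tested models in the list of assembly and stress factors, 14 were higher, 0 lower and 6 did not pass (15 higher adjusted over the list alone). USP14, a deubiquitinase bound to the proteasome, rose from 45.0 ± 4.34 to 83.6 ± 8.40 TPM (log2 fold change 0.88 ± 0.07, adjusted p = 1.75e-06). UFD1L, a cofactor of the segregase VCP, rose by 0.73 ± 0.07, and POMP, a chaperone of core assembly, by 0.74 ± 0.07. NFE2L1 (1 OF 2), a copy of a transcription factor known to drive proteasome genes, rose from 38.5 ± 2.47 to 51.3 ± 5.01 TPM (log2 fold change 0.40 ± 0.07). The list was called by camera (adjusted p = 4.29e-18; adjusted p = 0.0121 with an estimated correlation). Among 8 models of immunoproteasome subunits, activators and antigen peptide transporters, PSME2 (1.00 ± 0.23) and PSME3 (0.49 ± 0.13) rose and 6 did not pass, PSME4 (1 OF 2) among them at 0.28 ± 0.12 (adjusted p = 0.182, and 0.0172 without bortezomib replicate 8). Over the list alone the count was also 2. Camera called this list at an adjusted p of 0.0444, and with an estimated correlation the adjusted p was 0.48. Bortezomib replicate 3 had the highest score of this list, 0.971, and the call ended when bortezomib replicate 1, 3 or 8 or vehicle replicate 3, 4, 5, 6 or 7 was left out (adjusted p = 0.0516 to 0.143). The PSME3 call ended without any 1 of 11 fish, bortezomib replicates 2, 4, 5, 6, 7 and 8 and vehicle replicates 2, 3, 4, 7 and 8 (adjusted p of up to 0.0804), and after median-of-ratios scaling, upper-quartile scaling and quantile normalization (adjusted p = 0.0654, 0.0693 and 0.0636). Without the 4 fish with pituitary transcripts the calls of PSME2, PSME3 and the list ended (adjusted p = 0.0806, 0.0721 and 0.087), with log2 fold changes of 1.04 and 0.56 and a list mean of 0.33 against 0.36 with all fish.

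Immediate early genes, which neurons transcribe within minutes of activity, fell as a group. Of 41 tested models, 21 were lower, 0 higher and 20 did not pass (26 lower and 1 higher adjusted over the list alone). IER2 (2 OF 2) and IER2 (1 OF 2), copies of a rapidly induced gene, fell by 1.67 and 1.17 on the log2 scale, with IER2 (2 OF 2) at 36.1 ± 9.31 against 121 ± 43.4 TPM. FOS fell by 1.60 on the log2 scale (SE 0.18, adjusted p = 2.80e-05). DUSP1, a phosphatase of MAP kinases, EGR2A, a zinc finger factor, and ZFP36, an RNA-decay factor, fell by 1.49, 1.55 and 1.29. FOSB was 15.0 ± 3.61 against 23.8 ± 10.9 TPM (adjusted p = 0.228, and 0.00237 with the first principal component as a covariate) and ATF3 was 3.01 ± 1.24 against 4.02 ± 0.793 TPM (adjusted p = 0.253). Camera called the list lower (adjusted p = 6.68e-23; adjusted p = 0.0316 with an estimated correlation), and the list scores did not overlap, at -0.70 to -0.14 in bortezomib fish and -0.0012 to 0.49 in vehicle fish (two-sided exact permutation p = 0.0001554). The calls of EGR2A and ZFP36 ended when bortezomib replicate 6 was left out (adjusted p = 0.0589 and 0.0548), and also without vehicle replicate 2 and vehicle replicate 7, respectively. Without the 4 fish with pituitary transcripts the calls of DUSP1, EGR2A and ZFP36 ended (adjusted p = 0.0734, 0.142 and 0.158), with log2 fold changes nearer to 0, at -1.05, -1.30 and -0.84.

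**Figure D2:**
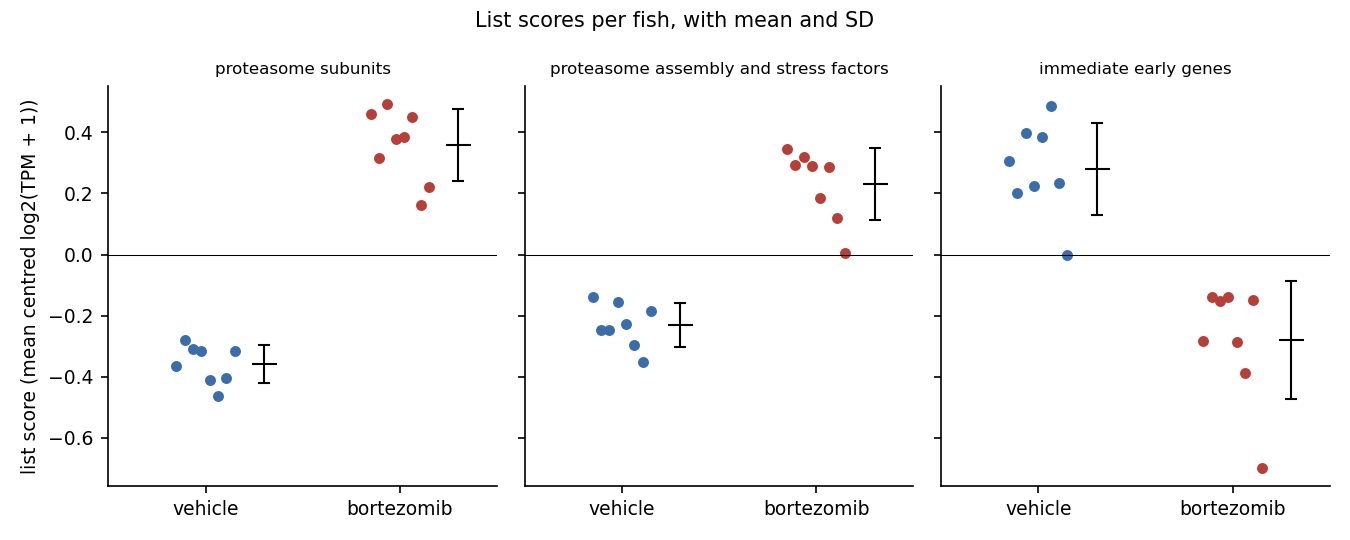
List score per fish (y axis, mean over genes of log2(TPM + 1) centred on all fish) by group (x axis) for proteasome subunits, proteasome assembly and stress factors, and immediate early genes. Points are fish, and the bar beside them is the mean with its SD; the 8 fish of each group do not overlap with those of the other group in these lists.

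The largest rises outside these groups were of genes with varied roles. DESI1, a desumoylating isopeptidase, rose 3.67-fold from 9.32 ± 4.35 TPM (log2 fold change 1.88 ± 0.26, adjusted p = 0.000365). PIP5KL1, a lipid kinase-like protein, rose by 1.44 ± 0.19, and GGH, a folate hydrolase, by 1.31 ± 0.30. ETHE1, a mitochondrial sulfur dioxygenase, rose by 1.19 ± 0.24, DPP3, a cytosolic dipeptidyl peptidase, by 1.11 ± 0.11, and PRKCBB, a protein kinase C, by 1.02 ± 0.24. FAM219A rose by 1.07 ± 0.28. The models mir-609 and mir-592 rose by 1.61 ± 0.40 and 1.57 ± 0.35. They are short models of repeated miRNA families, so their reads are uncertain. Allowing for relative depth, the values of each were low whole multiples of a step, so both rises rest on few reads per fish. In mir-609 vehicle replicates 4 and 8 were at 2.12 and 2.19 TPM and the other vehicle fish at 0 TPM. The largest falls outside the immediate early genes were of IGFBP1A, which binds insulin-like growth factors (5.09 ± 0.968 against 27.0 ± 24.6 TPM), and the transcription factors CEBPB (20.0 ± 5.82 against 75.0 ± 48.5 TPM) and CEBPD (49.4 ± 18.6 against 162 ± 97.3 TPM). They further included MUC17, a mucin, ALOX5AP, a protein of leukotriene synthesis, SIK1, a salt-inducible kinase, and DNAJB5 (2 OF 2), a J-domain chaperone (93.1 ± 17.3 against 229 ± 77.2 TPM). The log2 fold changes of MUC17, ALOX5AP, SIK1 and DNAJB5 (2 OF 2) were -1.47, -1.26, -1.24 and -1.23. Without the 4 fish with pituitary transcripts the calls of IGFBP1A, CEBPB, CEBPD, SIK1, MUC17, mir-609 and ETHE1 ended (adjusted p = 0.175, 0.102, 0.172, 0.119, 0.0771, 0.17 and 0.0514). The log2 fold changes were then -1.25, -1.22, -1.01, -0.87, -1.69, 1.37 and 1.30, those of MUC17 and ETHE1 larger than with all fish. Vehicle replicates 5, 6 and 7 were the 3 highest fish in IGFBP1A (45.7, 47.5 and 71.5 TPM, and at most 17.0 TPM in the other fish) and CEBPD (264, 285 and 269 TPM, and at most 155 TPM). The same 3 fish were highest in CEBPB, SIK1, DNAJB5 (2 OF 2), DUSP1, ZFP36, IER2 (2 OF 2), FOSB, GADD45BA and SOX17, which was noticed after the values were seen. Vehicle replicates 1 and 2 lay at 6.69 and 5.57 TPM of IGFBP1A and 80.4 and 40.3 TPM of CEBPD, near the bortezomib fish. Several calls also ended without 1 fish. For CEBPD this was bortezomib replicate 2, 6 or 7 or vehicle replicate 7 (adjusted p of up to 0.0541), and for mir-609 bortezomib replicate 2, 6 or 7 or vehicle replicate 2, 3 or 7 (up to 0.0602). For FAM219A it was bortezomib replicate 2, 4, 5, 6 or 7 or vehicle replicate 3, 4, 7 or 8 (up to 0.0737), and for IGFBP1A bortezomib replicate 1, 2, 4, 5, 6 or 7 or vehicle replicate 4, 5, 6 or 7 (up to 0.0673). For ALOX5AP it was bortezomib replicate 1, 2, 5 or 7 or vehicle replicate 3, 6, 7 or 8 (up to 0.0663), and for MUC17 any fish but bortezomib replicate 3 and vehicle replicates 1, 4 and 5 (up to 0.0877).

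**Figure D3:**
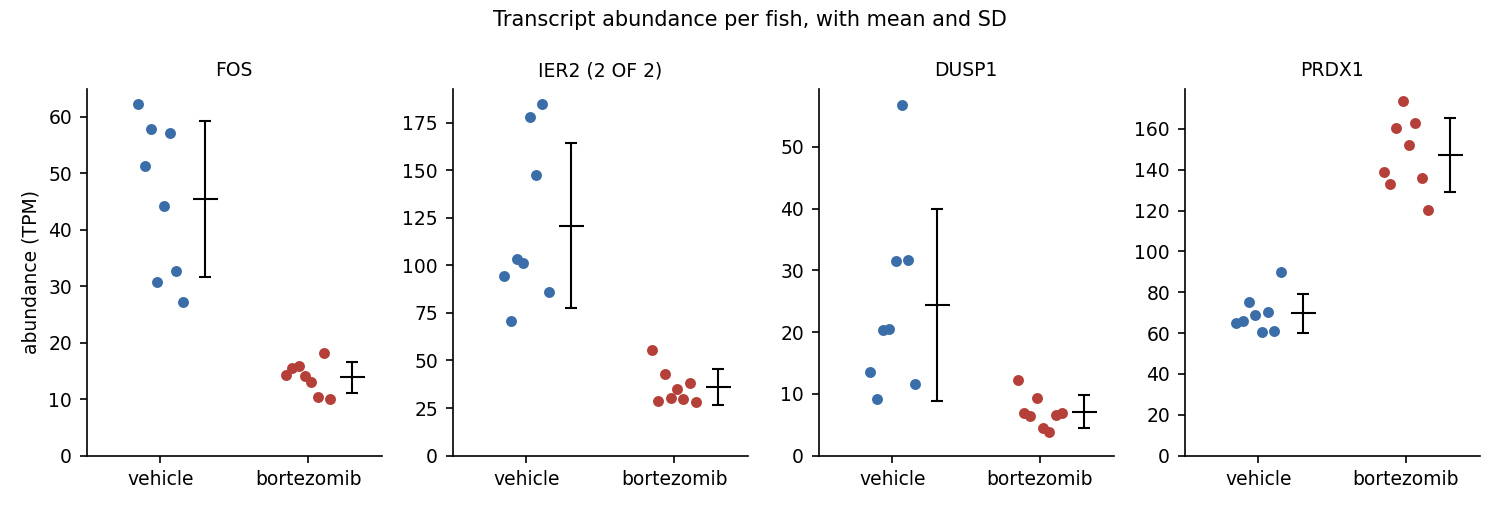
Abundance in TPM (y axis, starting at 0) of FOS, IER2 (2 OF 2), DUSP1 and PRDX1 in each fish, by group (x axis), with the mean and SD beside the points. FOS, at 13.9 TPM on average in bortezomib fish and 45.4 TPM in vehicle fish, was lower in all bortezomib fish than in any vehicle fish, and PRDX1 was higher.

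Some antioxidant genes rose, while cytosolic chaperones were not called as a list. Of 30 tested targets of the antioxidant factor NFE2L2, 6 were higher, 1 lower and 23 did not pass (13 higher and 4 lower adjusted over the list alone). PRDX1, a peroxiredoxin, rose from 69.7 ± 9.57 to 147 ± 18.0 TPM (log2 fold change 1.07 ± 0.09, adjusted p = 1.33e-06). GCLM, of glutathione synthesis, rose by 0.57 ± 0.10, and SOD1, a superoxide dismutase, by 0.37 ± 0.06 (adjusted p = 0.0536 after upper-quartile scaling). The lower gene was FTL, a ferritin chain, named after its values were seen. NFE2L2A itself was 6.54 ± 0.564 against 6.88 ± 0.902 TPM (adjusted p = 0.717) and HMOX1 4.45 ± 0.88 against 5.86 ± 1.12 TPM (adjusted p = 0.13). Camera called this list higher (adjusted p = 0.0178, and 0.48 with an estimated correlation). The list also passed by fry, a test of whether a list's genes move one way (adjusted p = 0.00376). It passed by exact permutation of the scores per fish as well (adjusted p = 0.0207). Cytosolic chaperones were not called (adjusted p = 0.678), with a mean log2 fold change of 0.048, a median of -0.013 and a mean of -0.010 after quantile normalization. Of 37 models 5 were higher and 1 lower, also over the list alone. These were DNAJA2, CCT6A, STIP1, CCT3 and CCT5 (higher, the CCT genes being subunits of a chaperonin) and DNAJB1B (lower), named after their values were seen. The more abundant HSPA8 model, a constitutive HSP70, was 3111 ± 162 against 3151 ± 434 TPM. The 2 HSPA1A models had log2 fold changes of -0.38 ± 0.23 and -0.22 ± 0.14, HSP90AA1.2 of -0.09 ± 0.08 and BAG3 of -0.21 ± 0.08, with adjusted p of 0.153 or more. The first HSPA1A value was -0.18 without vehicle replicate 6, and HSP90AA1.2 was at 0.0084 without the 4 fish with pituitary transcripts.

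Endoplasmic reticulum stress genes were called lower by camera (adjusted p = 0.0178; adjusted p = 0.48 with an estimated correlation; adjusted p = 0.0778 without vehicle replicate 2), although 1 of 26 passed the gene test: HERPUD1, of protein degradation at the endoplasmic reticulum, fell from 41.0 ± 4.08 to 32.1 ± 1.66 TPM (log2 fold change -0.34, and -0.35 with adjusted p = 0.0512 without the 4 fish with pituitary transcripts). SYVN1 and XBP1 had log2 fold changes of -0.27 ± 0.09 and -0.20 ± 0.08 (adjusted p = 0.0955 and 0.14), and the HSPA5 models of -0.28 ± 0.11 and 0.10 ± 0.19. The second HSPA5 model ran from -0.037 to 0.23 when 1 fish was left out. SYVN1 passed after median-of-ratios scaling, upper-quartile scaling and quantile normalization (adjusted p = 0.0343, 0.0355 and 0.0463), and the first HSPA5 model after quantile normalization (adjusted p = 0.0474). Of 27 targets of the amino acid response factor ATF4, CEBPB fell and 26 did not pass. Camera called that list lower at an adjusted p of 0.0318 (adjusted p = 0.387 with an estimated correlation). The list passed by exact permutation of the scores per fish (adjusted p = 0.0272) but not by fry (adjusted p = 0.128). The camera call ended after median-of-ratios scaling (adjusted p = 0.0558), after upper-quartile scaling (adjusted p = 0.0652), and without bortezomib replicate 2 or 7 or vehicle replicate 6 (adjusted p = 0.0545 to 0.0642). It also ended without the 4 fish with pituitary transcripts (adjusted p = 0.0964), as did the call of CEBPB. PSPH and ALDH1L2, of serine and folate metabolism, had log2 fold changes of 0.26 ± 0.08 and 0.52 ± 0.17 (adjusted p = 0.0811 and 0.0876). PSPH passed without bortezomib replicate 1 or vehicle replicate 8 (adjusted p = 0.0495 and 0.0399) and ALDH1L2 without bortezomib replicate 8 (adjusted p = 0.0443). DDIT3, a factor induced by unfolded proteins, was 64.5 ± 8.74 against 61.8 ± 12.2 TPM (adjusted p = 0.746). Over the list alone the counts of both lists were the same, 1 lower each. Of 31 targets of p53 and apoptosis genes 6 were lower and 25 did not pass (5 higher and 8 lower over the list alone). They included PLK2B (-0.55 ± 0.09), GADD45AA (-0.76 ± 0.13) and GADD45BA (-1.07 ± 0.22), which growth and stress signals also induce. The GADD45BA call ended without the 4 fish with pituitary transcripts (log2 fold change -0.90, adjusted p = 0.106). The mean of that list was -0.096, its median 0.0019, and camera called it lower at an adjusted p of 0.0493 (adjusted p = 0.48 with an estimated correlation). The call ended after median-of-ratios scaling, upper-quartile scaling and quantile normalization (adjusted p = 0.0992, 0.113 and 0.144), and without the 4 fish with pituitary transcripts (adjusted p = 0.158). With exact symbols only the mean turned to 0.039 (adjusted p = 0.935). It also ended without bortezomib replicate 2, 3, 5 or 7 or vehicle replicate 4, 5, 6 or 7 (adjusted p = 0.0538 to 0.142).

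A few lysosomal and mitochondrial genes rose. Of 57 lysosome genes 5 were higher and 0 lower (9 higher over the list alone), among them CTSD, a lysosomal protease (109.5 ± 7.71 against 82.6 ± 5.77 TPM), and ATP6V1C1 (1 OF 2) and ATP6V1B2 of the proton pump (0.28 ± 0.06 and 0.73 ± 0.18). NPC1 and ATP6V1H were the others, named after their values were seen. Of 36 autophagy genes 4 were higher, also over the list alone: GABARAPA, GABARAPL2, ATG7 and ATG5, named after their values were seen. The list was not called (adjusted p = 0.225), and SQSTM1, an autophagy receptor, was 60.8 ± 14.7 against 47.3 ± 3.73 TPM (adjusted p = 0.136). Without bortezomib replicate 8 the autophagy list and SQSTM1 passed (adjusted p = 0.0333 and 0.0384). Of 65 nuclear genes of oxidative phosphorylation 8 were higher (20 higher and 1 lower over the list alone), with COX6B1 at 0.41 ± 0.06, ATP5H at 414 ± 25.7 against 331 ± 23.7 TPM, and NDUFS4 at 0.20 ± 0.05. Of 64 mitochondrial ribosomal proteins 4 were higher (6 over the list alone), among them MRPS16 (0.25 ± 0.05), MRPS18C (0.23 ± 0.05) and MRPS14 (0.22 ± 0.06), and MRPL28, named after its values were seen. Camera called lysosome, oxidative phosphorylation and mitochondrial ribosome higher at adjusted p of 0.0318, 0.000928 and 0.000798, and with an estimated correlation the adjusted p were 0.545, 0.518 and 0.48. By fry the adjusted p were 0.143, 0.0808 and 0.0377. By exact permutation of the scores per fish they were 0.244, 0.073 and 0.00816, so the mitochondrial ribosome list passed both. Quantile normalization ended these 3 camera calls (adjusted p = 0.144, 0.492 and 0.146). Median-of-ratios scaling ended the first and second (adjusted p = 0.0793 and 0.073) and upper-quartile scaling all 3 (adjusted p = 0.106, 0.113 and 0.0741). Sample quality weights also ended the first and second (adjusted p = 0.119 and 0.0724). The first component of the residuals as a covariate ended the lysosome call (adjusted p = 0.080). Single omissions ended the lysosome call (bortezomib replicate 1 or 3 or vehicle replicate 5 or 6, adjusted p = 0.0531 to 0.128) and the oxidative phosphorylation call (bortezomib replicate 8, adjusted p = 0.0643). They also ended the calls of ATP6V1B2 (bortezomib replicate 2, 4 or 6 or vehicle replicate 2, up to 0.0635), NDUFS4 (bortezomib replicate 6, 0.0524) and MRPS14 (bortezomib replicate 4 or 6 or vehicle replicate 3, 7 or 8, up to 0.0588). Median-of-ratios scaling, upper-quartile scaling and quantile normalization each ended the calls of MRPS16 (adjusted p = 0.0909, 0.123 and 0.0964), MRPS18C (0.0687, 0.104 and 0.0766), MRPS14 (0.163, 0.215 and 0.239) and NDUFS4 (0.186, 0.249 and 0.159). After quantile normalization MRPS16 was at 0.15 and MRPS14 at 0.12. The first and second of these scalings also ended the call of ATP6V1C1 (1 OF 2) (adjusted p = 0.0654 and 0.0799), and the second that of ATP5H (adjusted p = 0.0625). Without the 4 fish with pituitary transcripts the lysosome and oxidative phosphorylation calls ended (adjusted p = 0.05005 for both). So did those of ATP6V1C1 (1 OF 2), ATP6V1B2, MRPS16, MRPS18C, MRPS14 and NDUFS4 (adjusted p = 0.0778, 0.0533, 0.0759, 0.0867, 0.12 and 0.119), at log2 fold changes of 0.29, 0.85, 0.24, 0.21, 0.20 and 0.20.

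Cytosolic ribosomal proteins were called lower by camera (adjusted p = 2.73e-10), with a mean log2 fold change of -0.099, but the adjusted p was 0.518 with an estimated correlation and the scores per fish overlapped (two-sided exact permutation p = 0.16). Of 81 models 3 were lower and 2 higher, also over the list alone. RPL3 fell from 508 ± 49.4 to 429 ± 23.3 TPM and RPS4X from 1819 ± 183 to 1528 ± 104.5 TPM, while RPL22 (2 OF 2) rose from 537 ± 47.1 to 713 ± 61.4 TPM. RPL19 (2 OF 2) also rose, named after its values were seen. The RPL3 call ended without bortezomib replicate 4 or 6 or vehicle replicate 7 (adjusted p of up to 0.0656), and the RPS4X call without bortezomib replicate 2, 4, 6 or 7 or vehicle replicate 2, 6 or 7 (up to 0.0742). Both calls also ended after median-of-ratios scaling (adjusted p = 0.0635 and 0.109) and upper-quartile scaling (adjusted p = 0.0766 and 0.127), and without the 4 fish with pituitary transcripts (adjusted p = 0.0936 and 0.132, log2 fold changes -0.25 and -0.24). In the microtubule list 5 of 48 were higher and 1 lower (11 higher and 1 lower over the list alone), with TUBA1A, an alpha tubulin, at 0.57 ± 0.09, TBCA, a tubulin chaperone, at 0.27 ± 0.06 and NEFH, a neurofilament, at -1.01 ± 0.18 (adjusted p of camera 0.034, and adjusted p = 0.48 with an estimated correlation). STMN4 and 2 models of KIF5BA also rose, named after their values were seen. The microtubule call ended after upper-quartile scaling (adjusted p = 0.0626), after quantile normalization (adjusted p = 0.0729), and without bortezomib replicate 2, 3, 5 or 8 or vehicle replicate 2, 3 or 5 (adjusted p = 0.0516 to 0.0856). The TBCA call ended after median-of-ratios scaling, upper-quartile scaling and quantile normalization (adjusted p = 0.0835, 0.108 and 0.077), and without the 4 fish with pituitary transcripts (adjusted p = 0.0825, log2 fold change 0.27). The list call ended with exact symbols only (adjusted p = 0.0991). Spliceosome genes (4 of 61 higher, 10 over the list alone), translation factors (1 higher and 1 lower of 45; 2 and 3 over the list alone) and cholesterol synthesis genes (0 of 33 by limma, 8 higher and 4 lower at an unadjusted p under 0.05; 3 higher over the list alone) were not called, at adjusted p of 0.0511, 0.484 and 0.827. Named after their values were seen, the spliceosome genes were SNRPD3, HNRNPD, SNRPD2 and SNRPE and the translation factors ETF1 (higher) and EEF1DA (lower). The spliceosome list lay at the threshold: it was called without bortezomib replicate 4 or 8 or vehicle replicate 2, 3, 4 or 8 (adjusted p = 0.0329, 0.0271, 0.0321, 0.0323, 0.0264 and 0.027) and in 6 of 18 other alternatives. Its adjusted p was 0.173 after median-of-ratios scaling and 0.678 with an estimated correlation. The mean of the translation factors was 0.043, and -0.019 after quantile normalization. Cell cycle genes were called lower (adjusted p = 0.0178; adjusted p = 0.518 with an estimated correlation) with 0 of 48 past the limma test over all genes or over the list alone and 1 higher and 6 lower at an unadjusted p under 0.05. Without bortezomib replicate 1 or 2 the list call ended (adjusted p = 0.0808 and 0.0609). CCND1, CENPE and TPX2 had the smallest p among them, with log2 fold changes of -0.24 ± 0.09, -0.27 ± 0.12 and -0.37 ± 0.16.

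**Figure D4:**
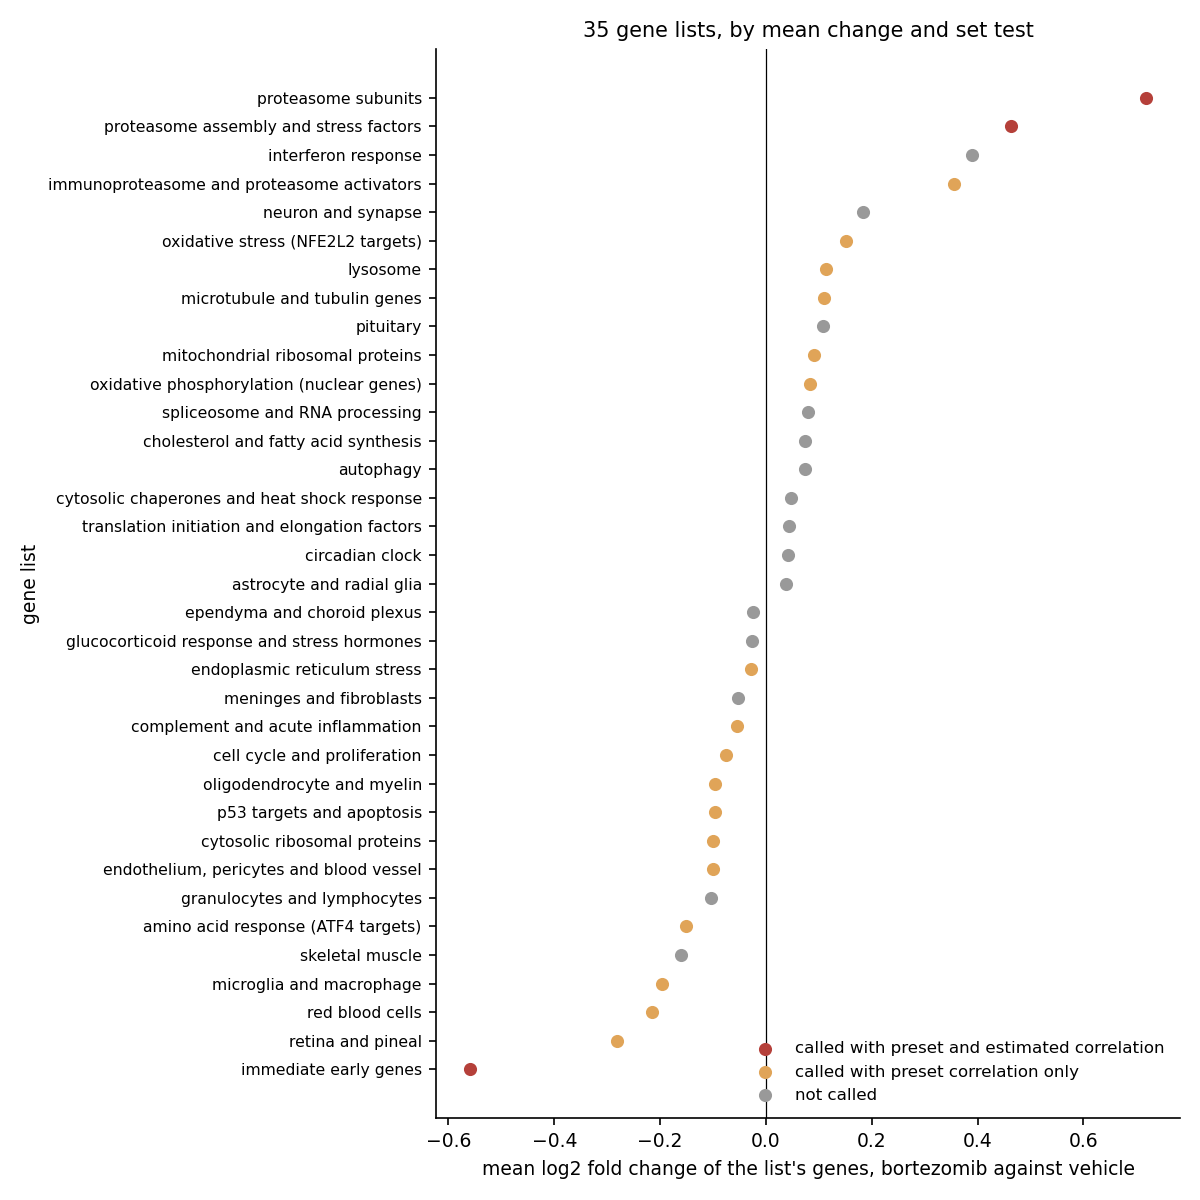
Mean log2 fold change of the genes of each of 35 lists (x axis, bortezomib against vehicle; y axis, list). Red lists were called by camera with the preset and with an estimated correlation between genes (3 lists), orange lists with the preset correlation only (17 lists), and grey lists were not called.

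Few markers of brain cell types and of neighbouring tissues passed the test. Of 103 neuron and synapse models 3 were higher, SNAP25 (2 OF 2), SYPB and RAB3AB, named after their values were seen, and 0 lower (1 higher over the list alone), and the list was not called (adjusted p = 0.225, and 0.0325 without the 4 fish with pituitary transcripts). In the oligodendrocyte list MAG, a myelin adhesion protein, rose by 0.76 ± 0.20 and FA2H, of myelin lipid synthesis, fell by 0.65 on the log2 scale, with 24 of 26 not passing (1 higher and 4 lower over the list alone). CLDN19 was at -0.31 ± 0.09 and the myelin protein MBPA at 3583 ± 947 against 5123 ± 978 TPM (adjusted p = 0.0533). CLDN19 passed after quantile normalization (adjusted p = 0.015) and without bortezomib replicate 3 or 4 or vehicle replicate 2 (0.0376, 0.0469 and 0.04), and MBPA without bortezomib replicate 1 or 8 or vehicle replicate 2 (0.0277, 0.0343 and 0.0453). The FA2H call ended without bortezomib replicate 2 or 5 or vehicle replicate 3 or 4 (adjusted p of up to 0.0537), and the MAG call without any fish but bortezomib replicates 3 and 8 and vehicle replicates 1, 4, 5 and 6 (up to 0.0828). Of 31 microglia models 0 passed by limma over all genes or over the list alone, with 0 higher and 8 lower at an unadjusted p under 0.05. IRF8, CORO1A and SPI1A, of myeloid cells, had log2 fold changes of -0.50 ± 0.14, -0.54 ± 0.16 and -0.33 ± 0.12, and AIF1 was at 23.4 TPM against 31.8 TPM on average (log2 fold change -0.42 ± 0.16, adjusted p = 0.132). IRF8 passed after median-of-ratios scaling, upper-quartile scaling and quantile normalization (adjusted p = 0.0341, 0.0356 and 0.0253) and without bortezomib replicate 3 or vehicle replicate 2 (0.0351 and 0.0418). CORO1A passed after quantile normalization (adjusted p = 0.0463) and without bortezomib replicate 3 or vehicle replicate 6 (0.0373 and 0.0411). In the vessel list RGS5B and SOX17 fell by 0.64 and 0.98 on the log2 scale, ABCB4 was at -0.33 ± 0.10, and 31 of 33 did not pass (3 lower over the list alone). Without the 4 fish with pituitary transcripts the calls of SOX17, FA2H, MAG and CNGB1 (2 OF 2), a retina gene, ended (adjusted p = 0.0836, 0.0577, 0.0693 and 0.121), at log2 fold changes of -0.79, -0.58, 0.92 and -0.54. ABCB4 passed after median-of-ratios scaling (adjusted p = 0.0464) and without vehicle replicate 6 (adjusted p = 0.0185). Camera called the oligodendrocyte, microglia, vessel, red blood cell and retina and pineal lists lower, at adjusted p of 0.00806, 0.000747, 0.0178, 0.0169 and 0.0115; with an estimated correlation the adjusted p were 0.48, 0.48, 0.48, 0.48 and 0.518. The vessel call ended without bortezomib replicate 2 or 3 (adjusted p = 0.057 and 0.0739). The red blood cell call ended after quantile normalization (adjusted p = 0.0548) and the retina and pineal call without bortezomib replicate 1 (adjusted p = 0.119). Sample quality weights also ended the red blood cell call (camera adjusted p = 0.0545), with a mean of -0.13 against -0.21 in the main fit. Of 15 red blood cell genes 0 passed by limma over all genes or over the list alone (1 higher and 6 lower at an unadjusted p under 0.05), with ALAS2, of haem synthesis, at -0.86 ± 0.29, GATA1A at -0.69 ± 0.26 and SLC4A1A at 0.38 ± 0.12. GATA1A passed without bortezomib replicate 5 (adjusted p = 0.012). Of 25 retina and pineal models CNGB1 (2 OF 2) fell by 0.51 on the log2 scale, also the 1 lower over the list alone. Its call ended without any fish but bortezomib replicates 3, 5 and 8 and vehicle replicates 2, 4 and 6 (adjusted p of up to 0.0774). ARR3 (1 OF 2) and NRL were at -0.56 ± 0.27 and -0.21 ± 0.11. Astrocyte and radial glia genes (0 higher and 2 lower of 34, SOX9A and GLUL (2 OF 2), named after their values were seen, also over the list alone) were not called (adjusted p = 0.438). The mean and median of that list were above 0 and camera's direction was down, with a mean of -0.019 after quantile normalization. GFAP, an astrocyte filament, was 296 ± 143 against 266 ± 70.4 TPM (adjusted p = 0.901), and its log2 fold change ran from -0.097 to 0.17 when 1 fish was left out.

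Inflammation and hormone lists showed few calls. Of 25 complement and inflammation genes the 2 copies of the inhibitor of NF-kappa-B, NFKBIAA and NFKBIAB, fell by 0.43 and 0.35 on the log2 scale, also over the list alone. The NFKBIAB call ended after upper-quartile scaling (adjusted p = 0.055) and without the 4 fish with pituitary transcripts (adjusted p = 0.12, log2 fold change -0.31). The cytokine receptor IL6ST was at 0.23 ± 0.09. Camera called the list lower at an adjusted p of 0.0406 (adjusted p = 0.48 with an estimated correlation). This call ended after median-of-ratios scaling, upper-quartile scaling and quantile normalization (adjusted p = 0.0939, 0.113 and 0.127), with exact symbols only (adjusted p = 0.141) and without the 4 fish with pituitary transcripts (adjusted p = 0.1795). It also ended without bortezomib replicate 2, 5 or 7 or vehicle replicate 5, 6 or 8 (adjusted p = 0.0552 to 0.142). Sample quality weights ended it too (adjusted p = 0.0611), with a mean of -0.0078 against -0.054 in the main fit. So did the first component of the residuals as a covariate (adjusted p = 0.0586). Of 21 interferon genes 1 passed, B2M (2 OF 2), named after its values were seen (2 over the list alone; list adjusted p = 0.0661). The interferon list was called after median-of-ratios scaling, upper-quartile scaling and quantile normalization (adjusted p = 0.0422, 0.0375 and 0.0445) and without bortezomib replicate 2, 5 or 7 or vehicle replicate 1 or 8 (0.0292, 0.0246, 0.0134, 0.0297 and 0.00872). Its mean of 0.39 became 0.14 without bortezomib replicate 3 (adjusted p = 0.602), whose score of 1.95 stood against at most 0.57 in the other bortezomib fish. With an estimated correlation its adjusted p was 0.715. Of 25 glucocorticoid genes CEBPD fell (2 higher and 4 lower over the list alone; list adjusted p = 0.224). The mean of this list was -0.027. Camera called it lower with exact symbols only (mean -0.094, adjusted p = 0.0421) and with the first principal component as a covariate (mean -0.26, adjusted p = 0.0136). FKBP5, a co-chaperone that glucocorticoids induce, varied from 0.354 to 78.9 TPM between fish and was 41.5 ± 28.9 against 26.3 ± 31.8 TPM (adjusted p = 0.397). Its log2 fold change was 1.28, and 0.82 to 1.68 when 1 fish was left out. It was -0.43 with the first principal component as a covariate (adjusted p = 0.388), and the adjusted p was 0.00135 with the first component of the residuals. The latter has no group difference by construction, so it leaves the fold change as it was. FKBP5 followed the first principal component at r of -0.98 within bortezomib fish and -0.96 within vehicle fish. The residual component may thus remove most of the spread of FKBP5 within groups, so that small p decides little. Of 35 clock genes 1 was higher, TEFB, named after its values were seen, and 1 lower (2 higher and 3 lower over the list alone; list adjusted p = 0.678, with a mean of 0.042, or -0.0075 after quantile normalization, and camera's direction down), and PER1 was 17.8 ± 5.49 against 22.7 ± 3.24 TPM (adjusted p = 0.208). The mean of the clock list ran from 0.010 to 0.091 when 1 fish was left out. The lists of meninges, skeletal muscle, granulocytes and lymphocytes, pituitary, and ependyma had adjusted p of 0.0531, 0.0914, 0.296, 0.432 and 0.224, and by limma 1 call among them, a fall of MYLPF (1 OF 2) of muscle, named after its values were seen, also over the list alone. At an unadjusted p under 0.05 these lists had 0, 1, 1, 2 and 1 higher and 3, 4, 0, 0 and 3 lower members, and the ependyma list had a mean of -0.025 and a median of 0.0042. The ependyma mean ran from -0.051 to 0.0099 when 1 fish was left out. The meninges list was called without bortezomib replicate 1 or 6 or vehicle replicate 1 (adjusted p = 0.0114, 0.0455 and 0.0461). The muscle list was called without bortezomib replicate 1 or 8 or vehicle replicate 1, 2, 5 or 8 (adjusted p = 0.0479, 0.0386, 0.0362, 0.0482, 0.0325 and 0.0428).

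The share of all transcripts taken by the 10 most abundant genes was lower in bortezomib fish, at 7.10% ± 0.881 against 8.41% ± 0.659 (SD, n = 8 each; two-sided exact permutation p = 0.00606). The share of the 50 most abundant genes was 21.6% ± 2.00 against 24.0% ± 1.68 (exact permutation p = 0.019). The number of genes above 0 TPM was 23675 ± 157 against 23712 ± 115 (exact permutation p = 0.602).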

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

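The tests of 1 fish, of neurons, of handling, of scale, of depth and of the ribosomal score, and the comparison with other splits for the gene count and the proteasome list, were chosen only after the result was seen; the test with FKBP5 as a covariate and the splits for the number of lists were written beforehand. In all, 100 splits of the 16 fish into groups of 8 were drawn, the real one included. Only the real one gave as many changed genes (901, against at most 3 in another split). It alone also gave as small a camera p for the proteasome list (6.14e-68, against 2.54e-38 in another split). This argues against chance for both, but 100 splits cannot show a share under 1 in 100. For the number of called lists chance cannot be excluded: 5 of the 100 splits gave at least 20, the highest other split 21, and the median of the other splits was 12. Camera with the preset correlation thus calls many lists in groupings other than the treatment. The other splits mix bortezomib and vehicle fish unevenly and can carry part of the treatment difference. Their counts of genes and lists are therefore not those of fish without a treatment difference.

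The fall of immediate early genes did not rest on 1 fish, since the score difference of -0.56 (SE 0.086) was still -0.50 in the omission that brought it closest to 0. A lower share of neurons would lower neuron markers, and the neuron list score differed by 0.18 (SE 0.11) in the other direction. A difference in glucocorticoid state stays open: with FKBP5 as a covariate the difference was -0.57 (SE 0.095), which met the level set beforehand as counting against it, but FKBP5 hardly followed the score (r = -0.27, permutation p = 0.312) and so had little to remove. Handling or the time of sampling cannot be told apart from the treatment, because the labels give neither per fish, and 2 clock genes were called. An effect of bortezomib on neuronal activity or on transcription stays open and was not tested.

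The excess of rises among the called genes may reflect the scale of the TPM values. The share of higher calls was 74.3% as deposited, 58.1% after median-of-ratios scaling and 49.4% after quantile normalization. With log2 relative depth as a covariate the share was 74.2%, which met the level set as counting against a difference in depth. Relative depth hardly differed between bortezomib and vehicle fish (0.991 ± 0.0778 against 1.02 ± 0.163, two-sided exact permutation p = 0.712). The covariate thus had little to remove, and the share with it decides little. No biological explanation was tested, so an effect of bortezomib stays open, as does the lower share of the most abundant genes in bortezomib fish.

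For the lower ribosomal protein transcripts a factor that varies from fish to fish regardless of treatment stays open. The exact permutation p of the score was 0.16, and any value of 0.05 or more had been set as speaking for such a factor. A p of that size shows no such factor, only that the groups were not told apart by the score. The scale of the values leaves the question open: the mean difference closest to 0 after median-of-ratios scaling or quantile normalization was -0.048, with a standard error of the score difference of 0.0673. An effect of the drug was not excluded.

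Values of single fish that lay far from the other 7 of their group, by the gap to the nearest of them over the group's range, numbered 33 among 298 groups looked at, where chance gives about 1 in 20 groups (14.9). Bortezomib replicate 8 accounted for 12: it was lowest in the scores of autophagy (-0.398), spliceosome (-0.245) and immediate early genes (-0.698), in TPM of PIP5KL1 (14.2), PSME4 (1 OF 2) (11.4), IER2 (1 OF 2) (25.6), CNGB1 (2 OF 2) (0.917), the more abundant HSPA1A model (4.73) and PSMD11A (25.0), and in genes of at least 1 TPM (17826) and of at least 10 TPM (9624), and highest in MRPS14 (156 TPM). Vehicle replicate 6 was lowest in the meninges score (-0.162), DPP3 (20.4 TPM), PSME4 (1 OF 2) (11.2 TPM) and PSMD11A (24.7 TPM) and highest in the same HSPA1A model (32.1 TPM). Bortezomib replicate 3 was highest in the scores of the immunoproteasome list (0.971) and of interferon response (1.95) and lowest in FAM219A (18.9 TPM). Bortezomib replicate 4 was highest in the score of granulocytes and lymphocytes (0.403) and in IGFBP1A (7.22 TPM) and lowest in 1 HSPA5 model (88.3 TPM), and bortezomib replicate 2 was highest in the other (51.6 TPM). Bortezomib replicate 1 was lowest in the retina and pineal score (-1.56) and in XBP1 (76.7 TPM). Bortezomib replicate 5 was lowest in mir-609 (0 TPM) and highest in GATA1A (11.9 TPM). Vehicle replicate 2 had the highest relative depth (1.39) and RPL3 (611 TPM), vehicle replicate 5 the highest mir-592 (13.8 TPM), vehicle replicate 7 the lowest ALDH1L2 (10.8 TPM) and vehicle replicate 8 the lowest EGR2A (1.34 TPM).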

How the results depend on the processing

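The alternatives that were added after seeing the data are the pseudocounts, quantile normalization, sample weights, the robust variance, the component and depth covariates, and the omission of the 4 fish with pituitary transcripts. The count of 901 changed genes became 1653 at an adjusted p under 0.10, 491 with a replicate block, 1892 with sample quality weights, 2434 with the first component of the residuals as a covariate (a component with no group difference by construction), and 327 without the 4 fish with pituitary transcripts, of which 304 were among the 901. Leaving out single fish gave 487 (without bortezomib replicate 6) to 1114 (without bortezomib replicate 8). The cause of these shifts was not tested. No other set of 4 fish was left out for comparison, so the effect of fewer fish cannot be told apart from that of these 4. The number of called lists, 20, became 3 with an estimated correlation. It was 5 with fry, a test of whether a list's genes move one way, and 6 with exact permutation of the scores per fish. Besides those 3 lists, mitochondrial ribosomal proteins and NFE2L2 targets passed by both fry and permutation, and ATF4 targets by permutation. Single omissions gave 15 to 23 calls by camera. The lists of proteasome subunits, of assembly and stress factors and of immediate early genes kept their direction and their call under the alternatives run, with mean log2 fold changes of 0.64 to 0.77, 0.41 to 0.50 and -0.61 to -0.50. The list of p53 targets turned from -0.096 to 0.039 (adjusted p = 0.935) with exact symbols only. Of 67 named genes that were called, 33 kept the call under each alternative other than single omissions, 50 kept it under each single omission, and 0 reversed. Of the 67 calls, 28 ended without the 4 fish with pituitary transcripts, 18 with the replicate block, 12 after upper-quartile scaling, 11 with the first principal component as a covariate, 9 after median-of-ratios scaling, 8 with no filter on low values and 6 after quantile normalization. Sample weights ended 2, and a pseudocount of 0.1 ended 1. The replicate block ended those of mir-592, FAM219A, PRKCBB, IGFBP1A, CEBPD, DUSP1, MUC17, ZFP36, PSME2, ATP6V1C1 (1 OF 2), RPL3, RPS4X, MRPS18C, MRPS14, NDUFS4, FA2H, MAG and CNGB1 (2 OF 2). The first principal component ended those of mir-609, mir-592, PRKCBB, MUC17, ALOX5AP, ATP6V1B2, RPL3, RPS4X, TBCA, MAG and CNGB1 (2 OF 2), and among the lists those of endoplasmic reticulum stress, ATF4 targets, cell cycle, complement and inflammation, microtubules, and retina and pineal (adjusted p = 0.0654 to 0.185). Named models without a call gained it with sample weights (11), the first component of the residuals (12) and the first principal component (4). Sample weights ended the list calls of immunoproteasome, lysosome, oxidative phosphorylation, complement and inflammation, and red blood cells (camera adjusted p = 0.0545 to 0.119). They added calls of meninges and muscle (0.0239 and 0.0242). The first component of the residuals ended those of lysosome, p53 targets, and complement and inflammation (0.0586 to 0.080) and added meninges (0.0472). The labels do not say whether the replicate numbers pair the fish, and the values showed no clear pairing. Same-numbered fish correlated at -0.24 to 0.41 (mean 0.074, against -0.010 for fish with different numbers), with 3 of 8 pairs over 0.1. Of the bortezomib fish 0 correlated best with their own number. With 8 pairs a shared tank, day or batch cannot be excluded. The planned count-based tests, voom, surrogate variables from counts and thinned counts were not run, because the values are TPM. Absolute depth is unknown, and read numbers were not derived for each low gene. The steps of mir-609 and mir-592 leave them few reads per fish. Which other low genes were limited by counting was not determined.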

Other observations

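The gene families below were chosen by symbol after the table of all genes had been looked at, and the FKBP5 relation was noticed before it was tested, so these tests were chosen after seeing the data; the tests of the shared programme and of glucocorticoid genes were written before their results were seen, while the repeat of the first without FKBP5 was added afterwards. Of 17 families, 7 were called by camera with the preset correlation and 0 with an estimated correlation. Of 33 ubiquitin-conjugating enzymes (UBE2) 7 were higher and 0 lower, among them UBE2D1A at a log2 fold change of 0.59 and UBE2L3B at 0.32. Of 6 prefoldin subunits, which hand unfolded actin and tubulin to chaperonin, 4 were higher (PFDN2, PFDN5, VBP1 and PFDN4, at 0.56, 0.39, 0.27 and 0.27). Of 7 COP9 signalosome subunits 3 were higher, COPS4, COPS5 and COPS3, at 0.30, 0.30 and 0.20. Of 23 peroxiredoxin and thioredoxin genes 6 were higher, with TXNL1, a thioredoxin of the proteasome, at 0.66 and PRDX6 at 0.51. Camera gave adjusted p over 17 families of 1.14e-05, 2.06e-05, 0.00364 and 5.28e-06 for these 4, and with an estimated correlation adjusted p of 0.0998, 0.0998, 0.0998 and 0.0755, so none of the 4 held there.

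Of 46 ESCRT and VPS genes 9 were higher, with CHMP6 (1 OF 2) at 0.70 and CHMP1A at 0.63, and of 78 RAB GTPases 10, with RAB7, of late endosomes, at 0.58. Of 22 V-ATPase genes 3 were higher, ATP6V1C1 (1 OF 2), ATP6V1B2 and ATP6V1H (camera adjusted p = 0.00953; adjusted p = 0.392 with an estimated correlation). Of the 23 peroxiredoxin and thioredoxin genes 3, of the UBE2 genes 1, of the RAB genes 2 and of the V-ATPase genes 14 were also in a fixed list. The camera adjusted p of the ESCRT and RAB families were 6.68e-05 and 2.06e-05, and 0.317 for both with an estimated correlation. Of 72 RING finger genes 8 were called, in both directions (5 higher and 3 lower, camera adjusted p = 0.823). Of 59 F-box genes 3 were called (FBXO2 higher, FBXW7 and FBXO28 lower, camera adjusted p = 0.448). Of 102 models with the potassium channel prefix KCN 1 was higher (camera adjusted p = 0.283). It was KCNIP3B, which interacts with channels and is not a channel itself. Of 326 solute carriers 13 were called (10 higher and 3 lower, camera adjusted p = 0.767). Not called either were 52 ubiquitin-specific proteases (5 higher; adjusted p = 0.213), 35 sorting nexins (2 higher, SNX3 and SNX29; adjusted p = 0.303) and 18 genes of mitochondrial protein import (3 higher and 1 lower; adjusted p = 0.095). The same held for 25 dual-specificity phosphatases (1 higher and 3 lower; adjusted p = 0.112), 95 miRNA models (2 higher; adjusted p = 0.207) and 17 Kruppel-like factors (KLF2 lower; adjusted p = 0.319).

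Genes that rose with bortezomib outside the proteasome lists were tested for a programme shared with the proteasome genes, as a hypothesis. It would give them a higher correlation with the proteasome score among vehicle fish alone than uncalled genes of like abundance. The median correlation of the 616 genes was 0.00088 in vehicle fish, where 10000 random sets had a median of 0.33 and a 95th percentile of 0.37, which is percentile 0. Correlations across genes within 8 fish are not independent replicates. In bortezomib fish the median was 0.076 against 0.18 in random sets. The random sets were not alike in spread, with a median SD of 0.24 in uncalled and 0.21 in rising genes of vehicle fish, and the proteasome score followed FKBP5 in vehicle fish (r = -0.90). With FKBP5 removed and the spread matched too, the median was 0.35 against 0.30 in random sets of vehicle fish (percentile 99.2) and 0.15 against 0.061 in bortezomib fish (percentile 100). The outcome thus turned with the comparison, and the shared programme stays open.

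Pituitary hormone transcripts marked 4 fish, 2 of each group. GH1, growth hormone, was at 1678 and 1745 TPM in bortezomib replicates 6 and 7 and at 3582 and 1384 TPM in vehicle replicates 5 and 6, and at most 1.49 TPM in the other fish. PRL, prolactin, was at 541 TPM or more in these 4 fish and at most 12.8 TPM in the others.

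The first principal component, with 26.6% of the variance (group difference, two-sided exact permutation p = 0.0789), followed FKBP5 across the 16 fish. Computed without the glucocorticoid list it correlated with log2 FKBP5 at r = -0.96 (permutation p = 1e-05, the smallest the resamples can give) and rho = -0.91 (permutation p = 1e-05), with adjusted p of 0.00036 over 36 relations. The scores of the glucocorticoid list without FKBP5 (r = 0.64, permutation p = 0.00812; rho = 0.74, permutation p = 0.00171) and of the pituitary list (r = 0.62, permutation p = 0.0103; rho = 0.72, permutation p = 0.00222) also followed FKBP5, with adjusted p of 0.101 for r and 0.0266 for rho in both. Without the 2 farthest fish these r were 0.56 and 0.69. Within bortezomib fish they were 0.48 and 0.55 and within vehicle fish 0.86 and 0.74. Within vehicle fish 4 other scores had an r beyond 0.8 or -0.8 with FKBP5: proteasome subunits at r = -0.90 (-0.58 within bortezomib fish, 0.19 over all fish), p53 targets at 0.87 (0.090 and 0.42), microtubule genes at 0.86 (-0.22 and 0.55) and mitochondrial ribosomal proteins at -0.84 (0.29 and -0.046). These relations within a group were not tested. The neuron and synapse score had r = 0.62 (permutation p = 0.0112, adjusted p = 0.101) and rho = 0.60 (adjusted p = 0.145), with 0.39 without the 2 farthest fish, 0.20 within bortezomib fish and 0.75 within vehicle fish. The glucocorticoid and pituitary lists share POMCA, which was at 70.5 TPM or more in the 4 fish with pituitary transcripts and at most 8.49 TPM in the others. Without the 2 fish farthest from the median of FKBP5 the r of the component was -0.93, and it was -0.98 within bortezomib fish and -0.96 within vehicle fish. Of the other genes 1271 correlated with FKBP5 above 0.8 and 58 below -0.8, the neuronal genes RGS4 (r = 0.97) and SCN2B (r = 0.92) among the first, named after their values were seen. The 4 fish with pituitary transcripts were also the 4 highest in FKBP5. Bortezomib replicates 8 and 4, without high pituitary transcripts, came next. The relation of the component with FKBP5 was not tested without those 4 fish. A part of pituitary tissue carried over with the brain thus stays open. A glucocorticoid state that differs between fish is a candidate explanation and stays open too. The median r of 10 other glucocorticoid gene models with FKBP5 was 0.11, under the 0.2 that had been set beforehand as counting against it. The genes ran from -0.60 (PER1) to 0.52 (KLF9), a spread wide enough that the median alone does not settle it. Within vehicle fish alone KLF9, CEBPD, ERRFI1 (2 OF 2), ERRFI1 and DDIT4 (1 OF 2) followed FKBP5 at r of 0.83, 0.82, 0.79, 0.64 and 0.60, and within bortezomib fish at 0.048, -0.37, -0.12, 0.35 and 0.051. The remaining models, ZBTB16A, TSC22D3, SGK1, PDK4 and PER1, were at 0.078, -0.095, -0.42, -0.42 and -0.69 within vehicle fish. Within bortezomib fish they were at -0.10, 0.15, -0.43, -0.60 and -0.56. These r were not tested, and the margin for that spread was added after the value had been seen. The r within vehicle fish include vehicle replicates 5 and 6, which had pituitary transcripts and the highest FKBP5. They were not repeated without these fish.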
